A study of Homo sapiens with 27 samples.

How the data were processed

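RNA was measured in 27 libraries from 2 human endometrial cancer cell lines, KLE and HEC-1-A, in 9 groups of 3. KLE came as 2 sets, with and without the label PIGR transduction. Per the labels' protocols, cells in medium with 2% serum were left untreated or given IgA or IgG at 0.5 µg/mL for 72 hours. RNA was isolated on micro columns with DNase treatment, and libraries were made with a kit designed for RNA from fixed tissue, per the labels' protocols.

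The deposited values are raw counts per gene in 3 tables, 1 per set of cells. Per the submitters' processing notes, reads were handled with bcl2fastq 2.20.0.422 and cutadapt 1.8.1 and refer to the genome build hg19. The aligner, the counting program, the annotation and the use of strand are not given in the sources used here. Reads shared by near-identical genes and by overlapping genes on opposite strands therefore cannot be assigned with certainty. Total counts ran from 13.4 to 57.8 M in KLE, from 22.0 to 42.9 M in KLE labelled PIGR transduction and from 30.1 to 44.6 M in HEC-1-A.

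The KLE table repeated 2055 rows with the same name and values, and each was kept once. Both KLE tables held 26 names that a spreadsheet had turned into dates. From the intact names of the HEC-1-A table, 24 were restored, and the 4 rows that could not be assigned were left out (0.0038% and 0.003% of counts). This left 55761 gene names in each KLE table and 55765 in the HEC-1-A table. No pair of libraries within a group agreed closely enough to be 1 library counted again: the lowest chi-square per gene between a pair was 5.3 in KLE, 5.61 in KLE labelled PIGR transduction and 12.4 in HEC-1-A.

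Genes were tested with edgeR 4.0.16 in R 4.3.3, using its default expression filter, TMM scaling and the robust quasi-likelihood test. Adjusted p is Benjamini-Hochberg over all genes tested in a comparison, and genes under 0.05 are called. Each table was fitted alone on its 9 libraries, giving 19041 genes in KLE, 18046 in KLE labelled PIGR transduction and 16624 in HEC-1-A. The 18 libraries of both KLE tables (19878 genes), and the 18 libraries of KLE and HEC-1-A (21023 genes), were fitted together for comparisons between tables. In these joint fits the difference of 2 treatment effects was tested as such, with the spread between libraries pooled over both tables. There were 14 comparisons. Errors of log2 fold changes are standard errors from the fit, and levels are CPM after TMM scaling, as mean ± SD. The labels do not say whether the 3 replicates of a group were separate cultures, so the p-values measure only the spread between these samples.

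Before the data were examined, 30 gene lists with 659 genes were fixed. All but PECAM1 were found by name (658). Lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, and p was adjusted over the lists of a comparison. The same test with a correlation estimated for each list, and fry, were run as alternatives. For each list the number of members called over all genes tested is given, and in parentheses the number called when p was adjusted over the list alone. A list test that is past 0.05 at the preset correlation but not with the estimated one is reported with both p-values.

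The genes named were also chosen by a rule fixed beforehand. PIGR comes first. In each comparison of IgA with untreated or IgG, and of the 2 untreated KLE sets, up to 10 called genes with the highest and 10 with the lowest fold change follow. For the other comparisons up to 5 each way were taken. These genes had a mean of at least 1 CPM and no overlap between the libraries of the 2 groups compared, except for differences of effects, where overlap was not considered. Clone names, small RNAs and pseudogenes were passed over. Up to 4 members with the smallest p stand for each list. A few genes that the rule takes are not named here. Where fewer than 5 genes were called all are named, and where none was, the 3 with the smallest p. For a gene with no counts in a group the fold is a lower bound, computed against 3 counts over that group. Intervals are exact 95% Poisson intervals, and they and the floors cover counting error only.

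The tests were first tested on simulated counts with known changes. For IgA in KLE, 37 of 56 genes changed 2-fold were recovered (66.1%) in a fit of 18654 genes. In KLE labelled PIGR transduction it was 43 of 64 (67.2%) in a fit of 17563 genes, and in HEC-1-A 35 of 62 (56.5%) in a fit of 15734. For the difference of the IgA effects between the KLE sets it was 39 of 70 (55.7%) in a fit of 19267. Each share comes from a single simulated draw. The share of false calls was 4.3%, 8.2%, 8.4% and 7%.

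The alternatives were DESeq2 1.42.0, RLE scaling, no filter, a stricter filter (1 CPM in 3 libraries), libraries thinned to equal total counts, a fit on the 2 groups compared, the replicate number as a block and leaving out each library. Added after seeing the data were an offset for GC content and transcript length, alone and with the block, leaving out RN7SL1 and mitochondrial genes, and, for differences of effects, a Welch test in which each effect has the standard error of its own table. That test also scaled each table alone, so its fold changes differ slightly from those of the joint fit. GC content and length came from an annotation of a later genome build, matched by name for 84.2% to 85.7% of tested genes, and no coordinates were used. Levels of sex-linked transcripts were not analysed here.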

Results

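Gene expression was measured by RNA sequencing in the endometrial cancer cell lines KLE and HEC-1-A after exposure to immunoglobulins. IgA is the main antibody of mucosal surfaces, and its polymeric form is carried across epithelia by the polymeric immunoglobulin receptor, the product of PIGR. The design of the series compares KLE cells with and without PIGR transduction, and HEC-1-A cells, each untreated, with IgA and with IgG. The 27 libraries form 9 groups of 3, so that every mean and fold change below rests on n = 3 libraries per group. The median total was 37.4 M counts in KLE, 30.4 M in KLE labelled PIGR transduction and 37.7 M in HEC-1-A. KLE IgA replicate 2 had the lowest total, 13.4 M, and gave 24.7% of its counts to mitochondrial ribosomal RNA, against 0.62% to 1.24% in the other KLE libraries. The plot of genes called per comparison shows the size of each response.

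**Figure D1:**
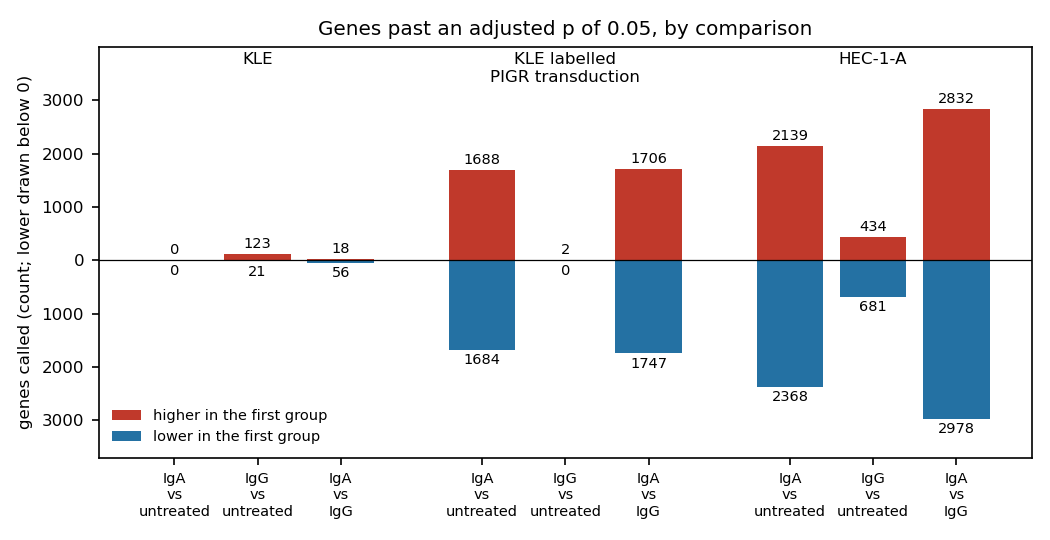
Genes past an adjusted p of 0.05 (y axis, number of genes, higher above and lower below 0) in each of 9 comparisons within a table (x axis). IgA called 0 genes in KLE, 3372 in KLE labelled PIGR transduction and 4507 in HEC-1-A, and IgG called 144, 2 and 1115.

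PIGR was close to the detection limit in both KLE sets and well expressed in HEC-1-A. The 9 KLE libraries held 43 PIGR counts among 333.2 M, or 0.129 CPM (95% interval 0.0934 to 0.174). The 9 libraries labelled PIGR transduction held 57 among 286.7 M, or 0.199 CPM (0.151 to 0.258). HEC-1-A stood at 41.8 CPM (41.1 to 42.4). Between the untreated KLE sets the log2 difference in PIGR was 0.47 ± 1.14 (adjusted p = 0.826), so the counts do not show the transduced gene. The titles of these libraries carry "PIGR_ve" with no sign, and the set is called KLE labelled PIGR transduction throughout. Every direction drawn from that label rests on the label alone.

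Other receptors that bind immunoglobulins were measured beside PIGR. TFRC, the transferrin receptor, was higher in untreated KLE labelled PIGR transduction than in untreated KLE (490 ± 4.32 against 343 ± 15.1 CPM, log2 0.52 ± 0.04, adjusted p = 1.35e-16). B4GALT1, a galactosyltransferase that also binds IgA at the cell surface, rose with IgA in KLE labelled PIGR transduction (0.37 ± 0.07, adjusted p = 0.00011) and in HEC-1-A (0.61 ± 0.07, adjusted p = 1.22e-08), and its log2 change in KLE was -0.02 ± 0.07. In HEC-1-A, IgA lowered PIGR itself from 44.9 ± 2.61 to 35.7 ± 4.10 CPM (log2 -0.33 ± 0.10, adjusted p = 0.016). FCAR, the IgA receptor of myeloid cells, had 0 counts in all 18 KLE libraries of both sets, where 3 counts would be 0.0519 to 0.224 CPM. As a list, the immunoglobulin receptors were not called in any comparison (smallest camera adjusted p = 0.265).

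In KLE cells, IgA was compared with no treatment to ask how the line responds without the transduction label. No gene passed. The 3 genes with the smallest p were HIST1H1D, a linker histone (log2 0.29 ± 0.05), RPL26, a ribosomal protein (0.24 ± 0.05), and SCARNA10, a small Cajal body RNA (0.30 ± 0.06), each at an adjusted p of 0.0926. HIST1H1D and RPL26 have close copies, so their counts are uncertain. edgeR called 0 of 19041 genes, with 912 at an unadjusted p under 0.05, and DESeq2 called 3. At the preset correlation, camera placed 5 lists past 0.05, with 0 members called over all genes tested. The mitochondrially encoded mRNAs (median log2 0.09, adjusted p = 0.0184), ribosomal proteins (0.03, adjusted p = 0.0184) and NRF2 targets (0.05, adjusted p = 0.0432) lay higher. The cholesterol synthesis list (-0.06, adjusted p = 0.0184) and the TNF and NF-kB targets (-0.05, adjusted p = 0.0432) lay lower. None of the 5 held, each at adjusted p = 0.679 with an estimated correlation. Adjusted over the list alone, 2 ribosomal proteins rose and 1 fell, and 1 NRF2 target rose. The gene count was 9 without the expression filter, 7 in a fit on these 2 groups, 5 without IgA replicate 1 and 3 without untreated replicate 1.

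IgG in KLE raised a small set of genes by modest amounts. HIST1H1D rose by a log2 of 0.50 ± 0.05 (adjusted p = 2.3e-07). PRG4, which encodes the lubricant lubricin, rose from 30.9 ± 1.87 to 52.9 ± 8.89 CPM (0.77 ± 0.10, adjusted p = 0.000431). HMGN5, a nucleosome-binding protein, rose by 0.73 ± 0.10 (adjusted p = 0.000148), the zinc finger gene ZNF836 by 0.65 ± 0.16 and the small heat shock gene HSPB6 by 0.62 ± 0.14. FAM72D had the highest change (1.11 ± 0.24), but it shares reads with near-identical copies. The 5 lowest were RAB23, a small GTPase (-0.38 ± 0.09), CLASP2, which binds microtubule ends (-0.33 ± 0.07), ATP6V0D1, a subunit of the vacuolar proton pump (-0.29 ± 0.07), TNIP1, an inhibitor of NF-kB signalling (-0.26 ± 0.06), and TBRG4 (-0.25 ± 0.06).

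In the same comparison 3 (13) of 13 mitochondrially encoded mRNAs rose (MT-ND4L 0.37 ± 0.07, MT-CO3 0.22 ± 0.05, camera adjusted p = 6.47e-19), and 3 (5) of 13 replication-dependent histones rose (HIST2H2BE 0.31 ± 0.05, camera adjusted p = 2.3e-06). Of 24 TNF and NF-kB targets 1 (1) fell (TNIP1, camera adjusted p = 0.00915), and of 18 lysosomal genes 1 (3) fell (ATP6V0D1, camera adjusted p = 0.00747). For these 4 lists adjusted p = 0.502 with an estimated correlation. Of the PERK-ATF4 stress list 2 (4) of 29 members fell, the amino acid transporter genes SLC7A5 (-0.19 ± 0.04) and SLC3A2 (-0.21 ± 0.05), at a camera adjusted p of 0.0484, and adjusted p = 0.545 with an estimated correlation. The parentheses here and below hold the counts adjusted over the list alone. Mitochondrially encoded mRNAs took 8.42% and 8.61% of counts in IgG replicates 1 and 2, 6.73% in replicate 3 and 6.29% to 6.68% in untreated libraries. edgeR called 144 genes, 123 higher and 21 lower, of which 3 exceeded 2-fold. The count was 449 without IgG replicate 3, and 51, 73, 52 and 64 without IgG replicate 2, IgG replicate 1, untreated replicate 3 and untreated replicate 2, and DESeq2 called 249.

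Set directly against IgG, IgA in KLE gave 74 called genes, 18 higher and 56 lower. The highest were the keratin KRT75 (0.65 ± 0.13), the Wnt inhibitor DKK1 (0.47 ± 0.11), the gamma-secretase subunit PSENEN (0.42 ± 0.09), the acetyltransferase KAT5 (0.34 ± 0.08) and the splicing factor SNRPB (0.31 ± 0.07). They were followed by the ribosomal protein genes RPL26, RPLP2, RPS14, RPS27 and RPL24 (0.18 to 0.23), whose counts pseudogene copies make uncertain. The lowest was HMGN5 (-0.68 ± 0.11), followed by the chloride transporter SLC12A5 (-0.64 ± 0.16). TXNDC17, GTPBP10, GPATCH4, ARHGAP33, FAM65A, IGFN1 and PSIP1, a chromatin-bound coactivator (-0.36 ± 0.05, adjusted p = 8.75e-05), lay between -0.42 and -0.36, as did ANKRD36, which has near-identical copies. Of the lists, 0 (11) of 13 mitochondrially encoded mRNAs fell (median -0.26, camera adjusted p = 1.63e-09), 1 (1) of 25 mitosis genes (HMMR -0.31 ± 0.06, camera adjusted p = 0.0062) and 1 (4) of 13 histones (HIST2H2BE -0.26 ± 0.05, camera adjusted p = 0.0107). The PERK-ATF4 list lay higher with 0 (0) of 29 members called (median 0.09, camera adjusted p = 0.000611), and the lysosome list with 0 (1) of 18 (0.04, camera adjusted p = 0.0497). All 5 had adjusted p = 0.716 with an estimated correlation. The gene count was 260 without IgG replicate 3, 28 without IgG replicate 2 and 29 without IgA replicate 3. It was 115 without the filter, 131 with DESeq2 and 113 with an offset for GC content and length.

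In KLE labelled PIGR transduction, IgA strongly raised genes of the PERK-ATF4 integrated stress response, which cells switch on when amino acids run short or unfolded protein builds up. STC2, a secreted glycoprotein of that response, rose 7.57-fold, from 31.0 ± 2.89 to 235 ± 11 CPM (log2 2.92 ± 0.06, adjusted p = 7.78e-35). The pseudokinase TRIB3 rose 6.48-fold (2.70 ± 0.12), the asparagine synthetase gene ASNS by 1.72 ± 0.07 and the tryptophanyl-tRNA synthetase gene WARS by 1.04 ± 0.05. Of the 29 list members tested 27 (28) rose and 0 (0) fell (median log2 1, camera adjusted p = 7e-159, and 5.12e-06 with an estimated correlation). The highest fold belonged to GDF15, a stress-induced cytokine, which rose 25.6-fold from 0.313 ± 0.206 to 7.94 ± 0.840 CPM (adjusted p = 3.79e-14). INHBE, an inhibin subunit, rose 10.6-fold, KLHDC7B 9.81-fold, the trypsinogen gene PRSS1 7.82-fold and CHAC1, which degrades glutathione, 6.61-fold. The peptide hormone gene ADM2 rose 6.20-fold, the collagen receptor DDR2 5.14-fold and the lysosomal membrane gene LAMP3 4.26-fold.

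Genes of low oxygen and sugar breakdown rose with them. Of 26 hypoxia and glycolysis genes 22 (22) rose and 0 (0) fell (camera adjusted p = 1.7e-39), among them the angiogenic factor VEGFA (1.40 ± 0.05), the mitophagy receptor BNIP3 (1.40 ± 0.11) and the glycolytic enzymes HK2 (0.90 ± 0.07) and PFKP (0.81 ± 0.05). Of 18 NRF2 targets 6 (6) rose, led by the ferritin genes FTH1 (0.57 ± 0.03) and FTL (0.30 ± 0.04) and the cystine transporter SLC7A11 (1.60 ± 0.11), with camera adjusted p = 3.51e-05. Among the TNF and NF-kB targets 9 (9) of 25 rose, led by the neutrophil chemokine IL8 (1.26 ± 0.08) and the adhesion molecule ICAM1 (0.32 ± 0.05), with camera adjusted p = 9.02e-05. Of 15 epithelial genes 6 (7) rose and 1 (1) fell (KRT7 0.99 ± 0.09, ELF3 1.14 ± 0.14, MUC1 0.54 ± 0.08, camera adjusted p = 0.000297). Of 15 YAP/TEAD targets 7 (8) rose and 2 (3) fell (CYR61 0.71 ± 0.04, AMOTL2 0.33 ± 0.04, camera adjusted p = 0.000627).

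Proliferation genes fell. Of 25 mitosis genes 21 (22) fell, such as the kinesin KIF20A (-0.70 ± 0.05) and the anaphase activator CDC20 (-0.45 ± 0.05), with camera adjusted p = 1.86e-22. Of 26 S phase genes 20 (21) fell, with RRM2, a subunit of ribonucleotide reductase, at -0.59 ± 0.06 and the flap endonuclease FEN1 at -0.51 ± 0.06 (camera adjusted p = 4.45e-15). All 13 (13) replication-dependent histones fell (HIST1H2BK -0.39 ± 0.04, HIST2H2BE -0.40 ± 0.04, camera adjusted p = 4.45e-15), although single histone genes share sequence and are uncertain. Of 25 cholesterol synthesis genes 13 (15) fell and 1 (1) rose, with the synthase HMGCS1 at -0.38 ± 0.05 (camera adjusted p = 1.36e-07). The 10 genes with the lowest fold change were DNAH3 (-1.90 ± 0.42), the estrogen sulfotransferase SULT1E1 (-1.78 ± 0.27), ENDOU, LRRTM1, the kinase BMX, TSACC, the lipogenic gene THRSP, the semaphorin receptor PLXNA4 (-1.46 ± 0.17), ARHGDIB and MOG. All of the lists of this paragraph and the 2 before it remained under 0.05 with an estimated correlation (0.00668 or less for stress, hypoxia, mitosis, S phase and histones, and 0.0147 to 0.0429 for the others).

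A further 5 lists passed only at the preset correlation. Of 46 ribosomal proteins 34 (37) rose by small amounts (median 0.14, camera adjusted p = 1.42e-09), with adjusted p = 0.143 with an estimated correlation. Of 23 antigen presentation genes 7 (9) rose and 1 (1) fell (HLA-B 0.45 ± 0.04, GBP1 -0.54 ± 0.09, camera adjusted p = 0.00218), with adjusted p = 0.17 with an estimated correlation. Of 40 type I interferon genes 5 (5) rose and 1 (1) fell (OASL 0.94 ± 0.18, BST2 0.85 ± 0.21, camera adjusted p = 0.0311), with adjusted p = 0.648 with an estimated correlation. Of 19 heat shock genes 12 (13) fell and 2 (3) rose (DNAJA1 -0.45 ± 0.04, HSP90AA1 -0.34 ± 0.03, camera adjusted p = 3.51e-05), with adjusted p = 0.12 with an estimated correlation. Of 32 nuclear-encoded oxidative phosphorylation genes 13 (19) fell and 1 (3) rose (NDUFS1 -0.29 ± 0.05, camera adjusted p = 0.000627), with adjusted p = 0.15 with an estimated correlation. The list of ER chaperones and ATF6/XBP1 targets was not called here or in any other comparison with IgA. In all, edgeR called 3372 of 18046 genes for IgA, 1688 higher and 1684 lower, and 219 of them changed more than 2-fold (140 higher, 79 lower).

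IgG in KLE labelled PIGR transduction changed 2 genes. RNY1, a small non-coding Y RNA, rose from 3.18 ± 0.844 to 7.56 ± 0.656 CPM (log2 1.24 ± 0.21), and RPS2P46, a ribosomal pseudogene, rose by 0.35 ± 0.06, both at an adjusted p of 0.00613. Pseudogene reads are shared with RPS2, so the second is uncertain. The TNF and NF-kB targets lay lower (median -0.17, camera adjusted p = 2.88e-05), with adjusted p = 0.222 with an estimated correlation. The ribosomal proteins (0.03, camera adjusted p = 0.000327) and the mitochondrially encoded mRNAs (0.13, camera adjusted p = 0.000607) lay higher, each at adjusted p = 0.82 with an estimated correlation. In these 3 lists 0 members were called over all genes tested, and 6 ribosomal proteins rose when adjusted over the list alone. The gene count was 0 without untreated replicate 3, IgG replicate 1 or IgG replicate 2, and 5 without untreated replicate 1. It was 10 with DESeq2, 28 without the filter, 39 in a fit on these 2 groups, 6 with a stricter filter and 4 with libraries thinned to equal totals.

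IgA against IgG in the same cells gave 3453 called genes (1706 higher, 1747 lower, 242 beyond 2-fold). The highest repeated GDF15 (15.9-fold), INHBE (11-fold), KLHDC7B (8.48-fold), ADM2 (8.42-fold), DDR2 (8.31-fold), STC2 (7.44-fold), TRIB3 (5.92-fold) and LAMP3 (4.44-fold), and added the calcium channel TRPV6 (6.42-fold) and LCN2, an iron-sequestering defence protein (4.42-fold, 24.8 ± 1.97 against 5.59 ± 0.563 CPM). The lowest included TXNIP, an inhibitor of glucose uptake, at 71.3 ± 5.15 against 184 ± 13.4 CPM (-1.37 ± 0.05, adjusted p = 1.14e-23), PLXNA4 (-1.82 ± 0.17), SULT1E1, MOG, ENDOU, LRRTM1, DDC, KCNJ16, TRIM43 and C21orf49. Of the stress list 27 (27) of 29 rose (camera adjusted p = 2.14e-152), and of the hypoxia list 22 (23) of 26 (7.03e-37). Of mitosis genes 20 (22) of 25 fell with 0 (1) up (5.27e-20), of S phase genes 20 (20) of 26 with 0 (1) up (1.75e-12), of histones 12 (13) of 13 (6.44e-12) and of cholesterol genes 13 (17) of 25, with 1 (2) up (1.59e-07). TNF and NF-kB targets rose in 12 (15) of 25 cases (IL8 1.35 ± 0.08, 5.29e-09). YAP/TEAD targets rose in 7 (8) of 15 cases with 2 (2) down (7.36e-05), NRF2 targets in 6 (8) of 18 with 1 (1) down (0.000283), and epithelial genes in 8 (8) of 15 (0.000942). With an estimated correlation these 10 stayed under 0.05, at 0.0414 or less.

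In that comparison 6 lists were lost with an estimated correlation. Of ribosomal proteins 21 (29) of 46 rose and 1 (1) fell (camera adjusted p = 3.51e-05, then adjusted p = 0.282 with an estimated correlation). Of heat shock genes 11 (13) of 19 fell and 3 (4) rose (0.000195), of oxidative phosphorylation genes 13 (16) of 32 fell and 1 (2) rose (0.000283), and of antigen presentation genes 10 (11) of 23 rose and 1 (1) fell (0.00069). For these 3, adjusted p = 0.141 with an estimated correlation. Of mitochondrially encoded mRNAs 5 (8) of 13 fell (0.00101, then adjusted p = 0.507 with an estimated correlation), and of type I interferon genes 6 (6) of 40 rose (0.00541, then adjusted p = 0.532 with an estimated correlation).

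HEC-1-A cells, which express PIGR, responded to IgA with a rise of inflammatory genes and a fall of lipid and proliferation genes. CCL22, a chemokine that attracts lymphocytes, rose 41.0-fold from 0.0878 ± 0.0958 to 3.7 ± 1.18 CPM (log2 5.36 ± 0.99, adjusted p = 0.000105). The cytokine genes LTB (8.62-fold) and TNF (7.20-fold) rose with it. Untreated, CCL22 and TNF (0.296 ± 0.326 CPM) had an SD above the mean, so the folds of both are uncertain. Of 25 TNF and NF-kB targets 16 (17) rose and 0 (1) fell (median 0.92, camera adjusted p = 3.02e-10), such as ICAM1 (1.75 ± 0.12), the chemokine CCL20 (1.17 ± 0.11) and the NF-kB inhibitor NFKBIA (0.77 ± 0.08). All 25 (25) cholesterol synthesis genes tested fell (median -0.92, camera adjusted p = 2.01e-65), among them FDPS (-1.58 ± 0.06), INSIG1 (-1.79 ± 0.07) and ACAT2 (-2.07 ± 0.09). SCD, which desaturates fatty acids, fell 5.26-fold from 676 ± 10.3 to 129 ± 19.6 CPM (-2.39 ± 0.08, adjusted p = 3.67e-16), and ACSL1, which activates them, fell 4.4-fold.

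Cell cycle lists fell in HEC-1-A as well. Of 25 mitosis genes 22 (22) fell and 1 (2) rose (HMMR -1.18 ± 0.07, KIF20A -0.90 ± 0.07, camera adjusted p = 1.95e-17), and of 26 S phase genes 17 (18) fell and 1 (1) rose (MCM6 -0.84 ± 0.07, PCNA -0.94 ± 0.07, camera adjusted p = 6.29e-13). Of 34 DNA repair genes 18 (20) fell (LIG1 -1.07 ± 0.09, FANCD2 -0.86 ± 0.08, camera adjusted p = 4.75e-05). Of 12 replication-dependent histones 10 (10) fell (median -1.08, HIST2H2BE -1.48 ± 0.06, camera adjusted p = 3.96e-37). Higher were 14 (15) of 26 hypoxia and glycolysis genes, with 0 (1) lower (NDRG1 1.05 ± 0.08, HK2 0.91 ± 0.11, camera adjusted p = 2e-06), and 7 (7) of 19 antigen presentation genes, with 0 (1) lower (the invariant chain CD74 0.82 ± 0.09, HLA-E 1.05 ± 0.14, camera adjusted p = 0.000454). YAP/TEAD targets rose in 8 (8) of 15 cases and fell in 2 (2) (ANKRD1 2.35 ± 0.28, CYR61 0.93 ± 0.06, camera adjusted p = 0.00114). Immediate early and ERK targets rose in 11 (12) of 23 cases and fell in 4 (4) (FOSL1 0.85 ± 0.06, DUSP6 -0.86 ± 0.11, camera adjusted p = 0.00441). These lists and those of inflammation and cholesterol kept an adjusted p of 0.0386 or less with an estimated correlation.

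Other high folds with IgA in HEC-1-A were those of the heat shock gene HSPA6 (13.4-fold), KLHDC7B (9.77-fold), SUN3 (9.09-fold), PHKG1 (8.69-fold), the matrix gene TNXB (8.62-fold) and the calcium release channel RYR1 (8.07-fold), all under 5 CPM with IgA, and MT1X, a metal-binding metallothionein with close paralogs (9.44-fold). The untreated level of HSPA6 was 0.207 ± 0.243 CPM, so its fold is uncertain. Other low folds were those of the mucin MUC5B (-2.32 ± 0.77), the tight junction gene CLDN2 (-2.25 ± 0.46), OIP5, TINAG, CEP112, RNF144A-AS1 and the fibrinogen chain FGB (-2.01 ± 0.23). Of the PERK-ATF4 list 20 (22) of 29 rose and 3 (3) fell (GDF15 2.5 ± 0.13, DDIT4 1.34 ± 0.09, STC2 0.93 ± 0.07, camera adjusted p = 5.7e-12), with adjusted p = 0.107 with an estimated correlation. Of 13 mitochondrially encoded mRNAs 11 (11) rose (MT-ND3 1.19 ± 0.15, camera adjusted p = 1.02e-07), with adjusted p = 0.26 with an estimated correlation, and their share of counts was 7.46% to 9.24% against 4.99% to 5.5% in untreated libraries. Of 19 heat shock genes 11 (11) fell and 2 (2) rose (HSP90AA1 -0.67 ± 0.06, camera adjusted p = 0.00114), with adjusted p = 0.0673 with an estimated correlation. edgeR called 4507 of 16624 genes, 2139 higher and 2368 lower, with 301 and 271 beyond 2-fold.

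**Figure D2:**
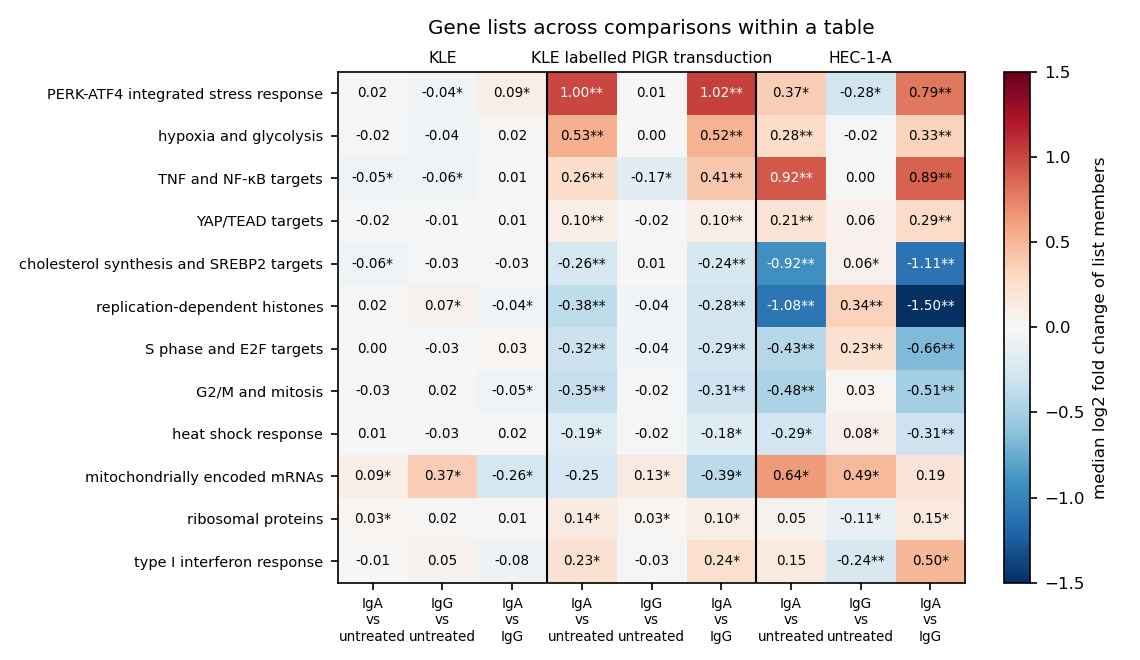
Median log2 fold change (colour scale) of 12 gene lists (rows) in the 9 comparisons within a table (columns), where 1 star marks a camera adjusted p under 0.05 and a second star marks that it held with an estimated correlation. The stress list had its highest median, 1.02, for IgA against IgG in KLE labelled PIGR transduction, and histones their lowest, -1.50, for IgA against IgG in HEC-1-A.

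IgG in HEC-1-A lowered interferon genes and raised S phase and histone genes. IFIT3 and IFIT1, antiviral genes that interferon induces, fell by a log2 of 1.28 ± 0.10 (adjusted p = 1.58e-10) and by 1.02 ± 0.13 (adjusted p = 1.83e-06). Of 34 type I interferon genes 6 (9) fell (camera adjusted p = 2.74e-05), and of 19 antigen presentation genes 4 (5) fell (HLA-C -0.35 ± 0.07, CD74 -0.42 ± 0.09, camera adjusted p = 0.000491). Of 26 S phase genes 6 (14) rose (CDC6 0.54 ± 0.07, camera adjusted p = 1.12e-09), and of 12 histones 8 (11) rose (HIST1H2BJ 0.78 ± 0.11, camera adjusted p = 2.69e-14). These 4 lists held with an estimated correlation, each at 0.0424. The highest folds were those of GFOD1 (3.69-fold), HIST1H4H (2.86-fold), FAM222A (2.79-fold), the RNA-binding CELF5 (2.5-fold) and HIST1H2BF (2.42-fold, 139 ± 6.83 against 57.4 ± 12.8 CPM). The lowest were FAM131C (-2.07 ± 0.54), the proteoglycan SPOCK2 (-1.88 ± 0.23), the stress gene NUPR1 (-1.76 ± 0.36), IL1RAPL1 (-1.57 ± 0.40) and MYO15B (-1.55 ± 0.40). Histone genes are uncertain one by one.

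The remaining 11 lists called for IgG in HEC-1-A did not hold with an estimated correlation. Of PERK-ATF4 genes 15 (18) of 29 fell (DDIT4 -0.88 ± 0.09, GDF15 -0.96 ± 0.14, ASNS -0.68 ± 0.10, camera adjusted p = 2.06e-19), and of epithelial genes 6 (7) of 19 fell (CLDN4 -0.77 ± 0.07, KRT19 -0.50 ± 0.06, camera adjusted p = 1.97e-06), both with adjusted p = 0.0739 with an estimated correlation. Of mitochondrially encoded mRNAs 6 (7) of 13 rose (MT-ATP6 0.76 ± 0.09, 4.75e-12), of ER chaperones 7 (10) of 24 rose and 2 (2) fell (HSPA5 0.28 ± 0.06, 0.000491), of heat shock genes 3 (4) of 19 rose (CHORDC1 0.63 ± 0.09, 0.00923), of DNA repair genes 2 (3) of 34 rose and 0 (1) fell (RAD51C 0.34 ± 0.09, 0.0394), and of p53 targets 3 (4) of 19 fell and 0 (1) rose (TNFRSF10B -0.38 ± 0.09, 0.00328). For these 5, adjusted p = 0.152 with an estimated correlation. The mitochondrial share of counts was 5.24% to 7.27% with IgG. Of ribosomal proteins 13 (17) of 46 fell (RPL3 -0.32 ± 0.05, 5.65e-07, then adjusted p = 0.244 with an estimated correlation), and of lysosomal genes 4 (4) of 18 fell (CTSB -0.45 ± 0.06, 0.00328, then adjusted p = 0.103 with an estimated correlation). Of ERK targets 6 (6) of 23 fell and 1 (2) rose (DUSP5 -0.53 ± 0.06, 0.0317, then adjusted p = 0.126 with an estimated correlation), and of cholesterol genes 4 (5) of 25 rose and 1 (1) fell (TMEM97 0.43 ± 0.07, 0.0226, then adjusted p = 0.203 with an estimated correlation). edgeR called 1115 genes, 434 higher and 681 lower, with 47 beyond 2-fold. The count was 658 without IgG replicate 2 and 740 without untreated replicate 2.

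IgA against IgG was the widest contrast within HEC-1-A, with 5810 called genes (2832 higher, 2978 lower, 1154 beyond 2-fold). The highest were CCL22 (48.0-fold), CGNL1 (23.3-fold), the phosphatase PTPRR (22.6-fold), RYR1 (22.2-fold), SUN3 (18-fold), the autophagy gene ATG9B (17.4-fold), TNXB (13.2-fold), the inflammasome gene NLRP1 (12.4-fold), NUPR1 (11.8-fold, 9.67 ± 0.730 against 0.809 ± 0.463 CPM) and APOL3 (11.6-fold). All 10 lay under 1 CPM with IgG. CCL22 (0.0699 ± 0.121), CGNL1 (0.0986 ± 0.171) and ATG9B (0.243 ± 0.421) had 0 counts in 2 of 3 IgG libraries, and PTPRR (0.273 ± 0.445) and TNXB (0.157 ± 0.172) also had an SD above the mean, so the folds of these 5 are uncertain. Among the lowest, HIST1H2BM had 0 counts with IgA and 309 with IgG over 3 libraries, at least 120-fold lower, and HIST1H4B (-2.70 ± 0.16), HIST1H2BF (-2.73 ± 0.23) and HIST1H1T fell too. The fold of HIST1H2BM rests on zeros in HEC-1-A, so it is uncertain too, for the reason given below. The other low genes were ZSWIM5 (-3.60 ± 0.86), FBXL19-AS1, RNF144A-AS1, FGB (-2.87 ± 0.23), OIP5 and the matrix gene NPNT (-2.71 ± 0.26). Of cholesterol genes 24 (25) of 25 fell (camera adjusted p = 5.92e-50), of histones 11 (11) of 12 (1.45e-42), of S phase genes 23 (23) of 26 with 1 (1) up (4.4e-18), of mitosis genes 21 (21) of 25 with 2 (2) up (2.35e-14), of DNA repair genes 21 (23) of 34 with 3 (3) up (1.82e-05) and of heat shock genes 12 (13) of 19 with 2 (2) up (0.000101). Of PERK-ATF4 genes 24 (24) of 29 rose and 2 (2) fell (9.83e-22), of TNF and NF-kB targets 15 (15) of 25 with 1 (1) down (7.29e-07), of hypoxia genes 15 (16) of 26 with 1 (1) down (5.47e-06) and of antigen presentation genes 12 (13) of 19 with 1 (1) down (8.34e-06). ERK targets rose in 12 (12) of 23 cases with 5 (5) down (0.000911) and YAP/TEAD targets in 8 (8) of 15 with 2 (2) down (0.00269). With an estimated correlation these 12 stayed at 0.0348 or less. Type I interferon genes (11 (12) of 34 up, 3 (3) down, camera adjusted p = 0.00597) had adjusted p = 0.0551 with an estimated correlation. Ribosomal proteins (24 (27) of 46 up, 2 (3) down, 0.0019) had adjusted p = 0.525 with an estimated correlation, and p53 targets (7 (7) of 19 up, 3 (3) down, 0.0262) had adjusted p = 0.283 with an estimated correlation.

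**Figure D3:**
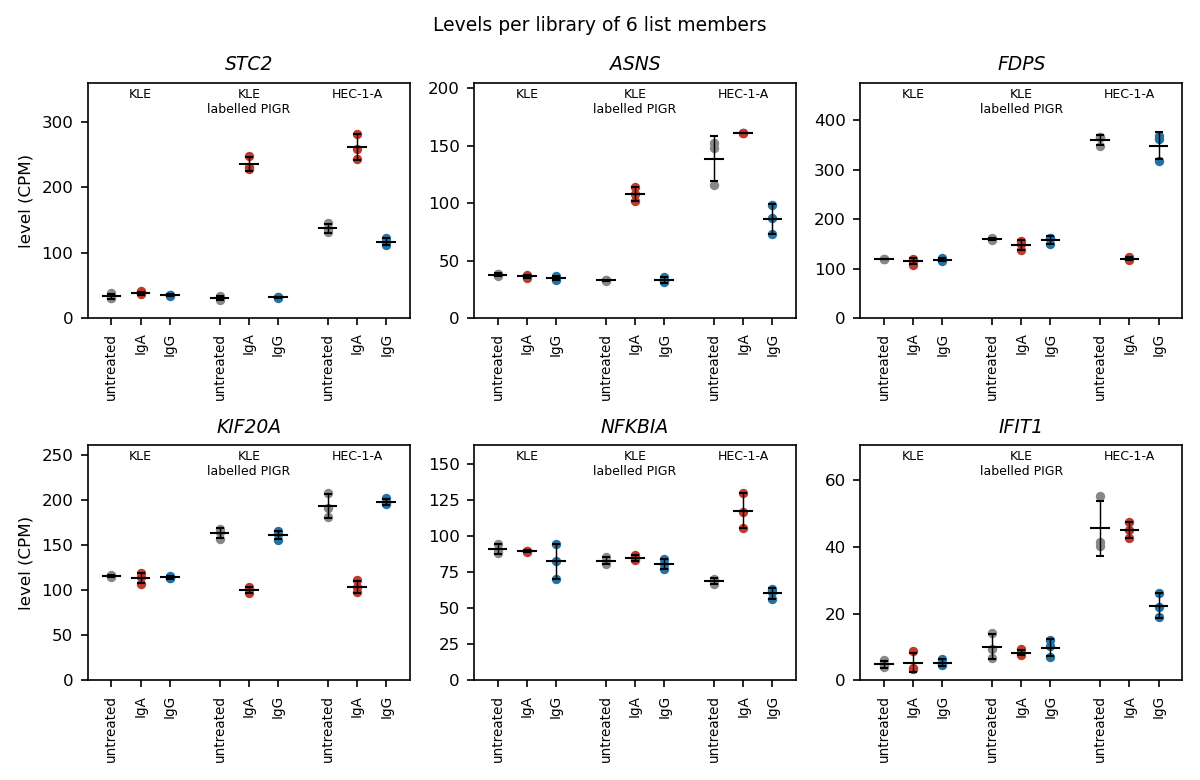
Levels in CPM (y axis) of 6 list members in each of the 27 libraries (points, by cell set and treatment), with the mean and SD of each group as bars. STC2 stood at 235 ± 11 CPM with IgA and 31.0 ± 2.89 CPM untreated in KLE labelled PIGR transduction.

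The untreated KLE sets differed from each other before any immunoglobulin was added. Untreated KLE labelled PIGR transduction had more cholesterol synthesis and mitosis transcripts and fewer epithelial and fibroblast marker transcripts. Of 25 cholesterol genes 20 (21) were higher (ACAT2 0.87 ± 0.05, HMGCS1 0.80 ± 0.05, camera adjusted p = 1.84e-23), and of 25 mitosis genes 23 (23) (KIF20A 0.54 ± 0.05, TOP2A 0.41 ± 0.04, camera adjusted p = 2.99e-14). Of 16 epithelial genes 11 (11) were lower and 0 (1) higher (KRT7 -1.71 ± 0.07, MUC1 -0.88 ± 0.07, CDH1 -0.44 ± 0.04, camera adjusted p = 1.16e-10). Of 7 fibroblast markers 4 (4) were lower and 1 (1) higher, with the collagen COL3A1 at -1.46 ± 0.04 and the proteoglycan DCN at -2.80 ± 0.12, 4.82 ± 0.292 against 33.5 ± 2.94 CPM (camera adjusted p = 3.91e-15). ZEB1, a repressor of epithelial genes, was 4.15-fold higher (2.05 ± 0.17, adjusted p = 1.19e-15), as were LIX1 (5.71-fold), the bile acid receptor NR1H4 (5.78-fold), ADAMTS12 (5.02-fold), TEX15, DDC, BACE2 and the GABA receptor GABBR2. The histone HIST2H4A (14.1-fold) has an identical copy, and TRBC2 rested on 1 library, with 1283, 37 and 7 counts in the 3 labelled libraries and 4 over the 3 others. The lowest were PHGR1 (14.7-fold), the metalloproteinases MMP12 (12.9-fold), MMP1 (8.91-fold) and MMP2 (6.98-fold), SHISA7 (10.1-fold), CYP1A1 (9.27-fold), FXYD3 (8.75-fold), the integrin ITGB6 (6.45-fold) and FSTL4 (6.36-fold).

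In that comparison of untreated sets, ERK targets were higher in 10 (12) of 24 cases and lower in 1 (2) (DUSP6 0.86 ± 0.07, FOS 1.31 ± 0.10, camera adjusted p = 2.89e-05), heat shock genes in 13 (13) of 19 with 2 (2) lower (3.34e-05), ER chaperones in 11 (11) of 25 (HSPA5 0.33 ± 0.04, 0.00117) and DNA repair genes in 15 (15) of 34 with 2 (2) lower (PARP1 0.41 ± 0.04, 0.0015). These and the 4 lists before them kept an adjusted p of 0.0413 or less with an estimated correlation. Mitochondrially encoded mRNAs were higher in 12 (12) of 13 cases (7.12e-09) and histones in 8 (9) of 13 (0.000262), both with adjusted p = 0.191 with an estimated correlation. Type I interferon genes were higher in 15 (15) of 40 cases with 1 (1) lower (0.00102, then adjusted p = 0.544 with an estimated correlation), S phase genes in 11 (12) of 26 with 1 (2) lower (0.00398, then adjusted p = 0.192 with an estimated correlation) and hypoxia genes in 9 (10) of 26 with 3 (3) lower (0.00448, then adjusted p = 0.0867 with an estimated correlation). Lysosomal genes were lower in 8 (9) of 18 cases with 1 (1) higher (CTSD -0.55 ± 0.04, 0.00448, then adjusted p = 0.242 with an estimated correlation). edgeR called 5172 of 19878 genes, 2734 higher and 2438 lower, with 601 beyond 2-fold. The 2 sets come from different tables, and each set is in 1 table only, so a batch of culture or sequencing cannot be told apart from the label.

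Whether the IgA effect differed between the KLE sets was tested directly. The stress genes led the difference. STC2 responded more in the labelled set by a log2 of 2.73 ± 0.10 (adjusted p = 3.2e-33), GDF15 by 4.43 ± 0.60, KLHDC7B by 3.26 ± 0.24, INHBE by 3.17 ± 0.64, ADM2 by 2.74 ± 0.38 and PRSS1 by 2.73 ± 0.53. The lowest differences were those of the serotonin receptor HTR1B (-2.39 ± 0.60), DNAH3 (-2.30 ± 0.58), BMX (-2.09 ± 0.58), SULT1E1 (-2.01 ± 0.37) and ARHGDIB (-2.01 ± 0.63). Of the PERK-ATF4 list 25 (27) of 29 had a higher response (camera adjusted p = 2.2e-117), of hypoxia genes 18 (22) of 26 (VEGFA 1.47 ± 0.08, 8.57e-35), of TNF and NF-kB targets 8 (8) of 25 (IL8 1.43 ± 0.13, 6.15e-06), of epithelial genes 5 (5) of 16 with 0 (1) lower (0.000679), of YAP/TEAD targets 6 (7) of 15 with 1 (1) lower (0.00184) and of NRF2 targets 4 (4) of 18 (0.00733). A lower response was found in 16 (19) of 25 mitosis genes (KIF20A -0.68 ± 0.07, 1.25e-16), 14 (20) of 26 S phase genes (3.07e-15), 10 (11) of 13 histones (2.25e-15) and 5 (8) of 32 oxidative phosphorylation genes with 0 (2) higher (0.000105). These 10 stayed at 0.0484 or less with an estimated correlation.

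In the same test of the difference, ribosomal proteins had a higher response in 10 (14) of 46 cases (0.000173, then adjusted p = 0.262 with an estimated correlation), antigen presentation genes in 6 (7) of 25 with 1 (2) lower (0.0033, then adjusted p = 0.107 with an estimated correlation) and type I interferon genes in 2 (2) of 40 (0.0263, then adjusted p = 0.655 with an estimated correlation). Cholesterol genes had a lower response in 8 (9) of 25 cases with 1 (1) higher (0.000412, then adjusted p = 0.107 with an estimated correlation), heat shock genes in 9 (12) of 19 with 2 (2) higher (0.000628, then adjusted p = 0.0804 with an estimated correlation), mitochondrially encoded mRNAs in 1 (5) of 13 (0.00662, then adjusted p = 0.537 with an estimated correlation) and DNA repair genes in 5 (7) of 34 with 0 (1) higher (0.0364, then adjusted p = 0.104 with an estimated correlation). edgeR called 1796 genes, 920 with a higher and 876 with a lower response in the labelled set.

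The IgG effect differed between the KLE sets in 10 genes, all with a lower response in the labelled set. The 5 lowest were HMGN5 (-0.67 ± 0.13), IGFN1 (-0.59 ± 0.12), the fatty acid binding gene FABP5 (-0.59 ± 0.10, adjusted p = 0.000778), HIST2H2BE (-0.48 ± 0.06, adjusted p = 6.03e-06) and GPATCH4 (-0.47 ± 0.09). Histones (1 (2) of 13 lower, camera adjusted p = 5.85e-06) and mitochondrially encoded mRNAs (0 (0) of 13, median -0.23, camera adjusted p = 3.59e-05) had adjusted p = 0.796 with an estimated correlation. The count was 53 without KLE IgG replicate 3, 19 without KLE untreated replicate 1, 16 without labelled untreated replicate 1, 6 without labelled untreated replicate 2 or labelled IgG replicate 1, 3 without KLE IgG replicate 1, and 2 without KLE untreated replicates 2 or 3, KLE IgG replicate 2, labelled untreated replicate 3 or labelled IgG replicate 3. It was 30 without the filter, 38 with DESeq2, 17 with libraries thinned to equal totals and 30 with the own spread of each table.

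The IgA effect was also set against that of KLE in HEC-1-A, the line that expresses PIGR. Cholesterol synthesis genes responded lower in HEC-1-A in 20 (22) of 25 cases (ACAT2 -2.01 ± 0.11, FDPS -1.49 ± 0.08, camera adjusted p = 1.47e-39), histones in 10 (10) of 13 (2.02e-22), mitosis genes in 16 (20) of 25 with 0 (2) higher (HMMR -1.12 ± 0.10, 2.44e-16), S phase genes in 17 (17) of 26 (1.93e-13) and DNA repair genes in 8 (9) of 34 (3.23e-05). A higher response was found in 11 (15) of 27 TNF and NF-kB targets (ICAM1 1.81 ± 0.12, LTB 3.58 ± 0.48, 5.28e-11), 12 (13) of 27 hypoxia genes (2.66e-06), 7 (7) of 15 YAP/TEAD targets with 1 (1) lower (ANKRD1 2.33 ± 0.15, 0.000165), 8 (8) of 24 antigen presentation genes (0.000486) and 11 (11) of 24 ERK targets with 3 (3) lower (0.00623). These 10 stayed at 0.0329 or less with an estimated correlation. Of single genes, MMP1, MICAL1, FGF1, COL16A1 and ATP10B had 0 counts in untreated HEC-1-A and 58 to 128 counts over the 3 IgA libraries, at least 20.7-fold to 45.7-fold higher. Their levels with IgA ran from 0.478 ± 0.451 (ATP10B) to 1.04 ± 0.914 CPM (MMP1), so the spread between libraries was about as large as the mean. RASSF8-AS1, CCM2L, MYLK4, ZGLP1 and LGALS2 had 0 counts with IgA and 37 to 95 untreated, at least 11.5-fold to 29.6-fold lower, with untreated levels from 0.278 ± 0.0567 (LGALS2) to 0.717 ± 0.363 CPM (CCM2L). Each HEC-1-A library held fewer genes with 1 to 5 counts (945 to 3878) than any library of the KLE tables (at least 4035), for a reason not given in the sources used here, so folds that rest on its zeros are uncertain. edgeR called 3082 of 21023 genes, 1689 with a higher and 1393 with a lower response. This fit pools the spread of both lines, whose common dispersion was 0.0827 in HEC-1-A and 0.00809 in KLE alone. For the median gene the coefficient of variation between libraries, beyond counting error, was 15.3% in HEC-1-A, 9.9% in KLE and 18.3% in the joint fit. Standard errors of the joint fit can therefore be too small for some genes of HEC-1-A and too large for others. When each effect had the spread and the scaling of its own table, 3287 genes were called, 1528 higher and 1759 lower. Of these, 2683 were among the 3082, and LGALS2 was not called (adjusted p = 0.0615). The scaling changed together with the spread, so the shift from higher to lower calls cannot be credited to the spread alone.

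For that difference a further 5 lists were lost with an estimated correlation. PERK-ATF4 genes responded higher in 15 (19) of 29 cases with 1 (3) lower (5.5e-07, then adjusted p = 0.129 with an estimated correlation), mitochondrially encoded mRNAs in 8 (10) of 13 (3.59e-07, then adjusted p = 0.236 with an estimated correlation), and mesenchymal and matrix genes in 4 (7) of 24 with 1 (1) lower (TGFBI 2.56 ± 0.42, THBS1 1.33 ± 0.22, 0.042, then adjusted p = 0.215 with an estimated correlation). Heat shock genes responded lower in 9 (10) of 19 cases with 3 (3) higher (0.00227, then adjusted p = 0.118 with an estimated correlation). Their median was -0.27 and their mean 0.03, with CRYAB, a small heat shock gene, at 2.46 ± 0.45. Oxidative phosphorylation genes responded lower in 7 (7) of 32 cases with 2 (2) higher (0.0309, then adjusted p = 0.51 with an estimated correlation).

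The IgG effect differed between HEC-1-A and KLE in 399 genes, 219 with a higher and 180 with a lower response in HEC-1-A. IFIT3 responded lower by a log2 of -1.50 ± 0.20 (adjusted p = 0.000366), DDIT4 by -0.90 ± 0.14 and KRT19 by -0.45 ± 0.07, and CDC6 responded higher by 0.59 ± 0.10. Of single genes, SYNC, EPHA10, LMOD1, AKR1B10 and CYP4X1 had 0 counts in untreated HEC-1-A and 16 to 42 over the 3 IgG libraries, at least 6.67-fold to 17.5-fold higher, with levels with IgG from 0.157 ± 0.137 (CYP4X1) to 0.372 ± 0.403 CPM (SYNC). ATAT1, CNKSR2 and CADPS2 had 0 counts with IgG and 26 to 46 untreated, at least 6.93-fold to 12.3-fold lower, with untreated levels from 0.19 ± 0.138 (CADPS2) to 0.348 ± 0.195 CPM (ATAT1), and ASPHD1 stood at 0.0186 ± 0.0322 against 0.975 ± 0.104 CPM. The folds against 0 counts are as uncertain here as those for IgA, and none of these 8 genes was called with the own spread of each table (adjusted p from 0.164 to 0.532). The pooled spread limits this count too: with the own spread 615 genes were called, 287 higher and 328 lower, of which 328 were among the 399. The count was 200, 202 and 180 without KLE untreated replicates 1, 2 and 3, 209 and 187 without KLE IgG replicates 1 and 2, and 247 without HEC-1-A untreated replicate 2. It was 728 without the filter and 1012 with DESeq2, and RLE scaling gave 187 higher and 298 lower.

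All 10 lists called for that IgG difference were lost with an estimated correlation. Higher responses were found in 2 (12) of 26 S phase genes (7.33e-10, then adjusted p = 0.114 with an estimated correlation), 2 (8) of 13 histones (3.18e-06), 2 (8) of 25 ER chaperones (5.16e-05), 3 (4) of 19 heat shock genes (0.00202) and 3 (3) of 25 cholesterol genes with 0 (1) lower (0.0228, then adjusted p = 0.5 with an estimated correlation). Lower responses were found in 6 (12) of 29 PERK-ATF4 genes (9.05e-09), 3 (4) of 19 epithelial genes (0.001), 1 (3) of 24 antigen presentation genes (0.00455) and 4 (11) of 46 ribosomal proteins (4.09e-07, then adjusted p = 0.395 with an estimated correlation). For histones, ER chaperones, heat shock, PERK-ATF4, epithelial and antigen presentation genes adjusted p = 0.148 with an estimated correlation. Of type I interferon genes 1 (2) of 41 responded lower and 0 (1) higher (0.00744, then adjusted p = 0.587 with an estimated correlation), with a median of -0.25 and a mean of 0.01.

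The 2 IgA responses were compared gene by gene, over the 14849 genes tested both in KLE labelled PIGR transduction and in HEC-1-A. Of these, 557 rose in both (215 for independent lists) and 647 fell in both (234), while 152 rose in the labelled KLE set and fell in HEC-1-A (239) and 118 did the reverse (210). Across genes, which are not independent replicates, Pearson's r of the fold changes was 0.156 and Spearman's rho 0.231. With a stricter filter r was 0.281. The IgA fold changes of KLE had an r of 0 with those of KLE labelled PIGR transduction and of -0.031 with those of HEC-1-A, which was 0.004 without HEC-1-A IgA replicate 2. The lists of pro-apoptotic genes, Mullerian lineage and steroid receptors, Wnt/beta-catenin targets, and lymphocyte, myeloid and endothelial markers were called in 0 of the comparisons in which they had enough tested members (14 for the first 3, then 2, 8 and 11), with smallest camera adjusted p of 0.511, 0.291, 0.125, 0.814, 0.449 and 0.306.

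IgA and IgG were each compared with the same untreated libraries, so their fold changes are correlated even where neither has an effect. Pearson's r across genes was 0.385 in KLE, 0.352 in KLE labelled PIGR transduction and 0.316 in HEC-1-A. It was 0.173 in KLE without IgA replicate 1, and 0.545 and 0.567 in HEC-1-A without untreated replicates 2 and 3, so these values move with single libraries. Simulated groups without any effect gave means of 0.462, 0.491 and 0.491. The covariance was 0.0546, 0.0701 and 0.29, against 0.0478, 0.0488 and 0.174 simulated, a difference of 0.00679, 0.0213 and 0.116. In HEC-1-A, Spearman's rho was 0.038, and with a stricter filter Pearson's r was -0.081. Of the HEC-1-A genes called in both comparisons 308 rose with IgA and fell with IgG (87.6 for independent lists), 205 fell with IgA and rose with IgG (61.8), 65 rose in both (55.8) and 83 fell in both (97). The simulated groups shared at most a mean of 0.15 called genes that rose in both, 0.05 that fell in both and 0 in opposite directions. They held no effect, so few genes could be called in them, and these means are no expectation for the overlap observed.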

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

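Apart from the regrouping of libraries, the tests in this part rest on results already seen. The search for exchanged labels among the KLE libraries was planned before, but its measure was the stress list shift seen with IgA in the labelled set. The other tests were chosen only after the result they concern was seen. The values of the next paragraph come from direct tests of whether an effect differed between 2 sets of cells.

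The IgA effect differed between KLE labelled PIGR transduction and KLE in 1796 genes and 17 lists, and the IgG effect in 10 genes and 2 lists. Between HEC-1-A and KLE the IgA effect differed in 3082 genes and 15 lists, and the IgG effect in 399 genes and 10 lists.

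IgA changed 3372 genes in KLE labelled PIGR transduction and 0 in KLE by edgeR (912 at an unadjusted p under 0.05, 3 by DESeq2). Lower depth of the KLE IgA libraries that hid a response as large as in the labelled set is argued against. With every library of the labelled set thinned to 13.4 M counts 2928 genes were still called, and 2834 with 10.1 M counts outside mitochondrial ribosomal RNA, as in KLE IgA replicate 2. The mitochondrial RNA of that replicate is argued against in the same sense, since the count without it was 0. A smaller response hidden by depth, or missed with that replicate left out, stays open. Exchanged labels among the 9 KLE libraries that hid a stress response as large as in the labelled set are argued against. Their mean stress list levels spanned 0.25 on the log2 scale, 19.5% of the 1.30 shift with IgA in the labelled set. An exchange that hid a smaller or another response would not show on this list, so exchanged labels in general stay open. A culture or library batch cannot be told apart from the label, since the untreated libraries of the 2 tables already differed in 5172 genes and each set fills 1 table. The transduction itself stays open as the biological explanation, untested.

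PIGR was near 0 in the libraries labelled PIGR transduction. Too little depth is argued against by an upper bound of 0.258 CPM in the labelled table. Exchanged KLE tables cannot be told apart from right ones by PIGR, which was near 0 in the table without the label too (upper bound 0.174 CPM). A transduced sequence whose reads the counting does not assign to PIGR cannot be told apart from an absent transcript, because the 57 counts are all that a gene table shows. A label that stands for cells without the receptor also stays open, untested, as the sign in the titles is missing.

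IgG called 144 genes in KLE. A trend with GC content and transcript length is argued against as the whole cause, since 178 genes were called with an offset for both. A departure shared by IgG replicates 1 and 2 may account for part of the calls: over the 449 genes called without replicate 3 (295 higher, 154 lower), that replicate lay at 37% of their distance from untreated (median log2 0.10 against 0.29 and 0.26). Genes chosen on 2 replicates place the one held out nearer to untreated in any case, so a shared departure and a common effect cannot be told apart by that value. The effect of IgG itself stays open, untested.

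To see whether chance could give such counts, the libraries of each comparison were regrouped and tested again. With 3 against 3 libraries there are 10 splits, too few for a share under 0.05. For KLE the real counts of genes were 0 for IgA, 144 for IgG and 74 for IgA against IgG, and the highest of the other splits gave 1, 3 and 5. As many genes as the real split came from 10, 1 and 1 of the 10 splits. For the other 7 comparisons of this kind the highest other split called 0 genes, against real counts of 3372, 2 and 3453 in KLE labelled PIGR transduction, 4507, 1115 and 5810 in HEC-1-A and 5172 between the untreated KLE sets, so 1 of 10 splits, the real one, reached each. The real numbers of lists, in the same order, were 5, 5, 5, 15, 3, 16, 13, 15, 15 and 14, and the highest others 3, 3, 5, 12, 4, 11, 11, 8, 14 and 9. As many lists came from 2 of 10 splits for IgA against IgG in KLE, from 4 of 10 for IgG in KLE labelled PIGR transduction and from 1 of 10 elsewhere.

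For differences of effects 100 splits were drawn, some of which kept the real groups of 1 set of cells and regrouped only the other. The highest other counts of genes all came from such splits, and splits that kept neither set called at most 1 gene for IgA and 1 for IgG between the KLE sets, and 11 and 8 between HEC-1-A and KLE. A regrouping of both sets asks whether either set responded, not whether the 2 responses differed. A regrouping of 1 set alone has 10 splits, too few for a share under 0.05, and the gene counts as large as the real ones came from splits of that kind. Chance is therefore not excluded for a difference of effects, and the shares below describe only the splits drawn. As many genes as the real 1796 for IgA between the KLE sets came from 2 splits (highest other 1800). As many lists as the real 17 came from 1 split (highest other 16), and both shares were under 0.05. For IgG between the KLE sets the share was under 0.05 for the 10 genes (3 splits, highest other 13). It was not for the 2 lists (56 splits, highest other 6). For IgA between HEC-1-A and KLE it was under 0.05 for the 3082 genes (3 splits, highest other 3243) and the 15 lists (4 splits, highest other 16). For IgG between these lines it was under 0.05 for the 399 genes (3 splits, highest other 476) and not for the 10 lists (9 splits, highest other 14).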

How the results depend on the processing

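The offset for GC content and length, the removal of RN7SL1 and mitochondrial genes and the use of each table's own spread were chosen only after the data were seen. The counts of genes for IgA in KLE labelled PIGR transduction (2546 to 3126 with 1 library left out), for IgA against IgG in that set (2736 to 3248), for IgA in HEC-1-A (3761 to 4184), for IgA against IgG in HEC-1-A (4960 to 5465), between the untreated KLE sets (4210 to 4507) and for both differences of the IgA effect (1417 to 1775 between the KLE sets, 2374 to 3264 between lines) stayed within 1.5 times under every alternative run. For the other results given here the cause was not tested. There were 11747 values of single genes under alternatives. Of these, 11129 stayed on their side of the threshold, 596 passed it no longer, 22 passed it newly and 0 reversed. These pooled numbers do not describe each comparison. For IgG in KLE 70 of 301 values passed it no longer, and 5 of 19 genes stayed on their side under every alternative. For IgA against IgG in KLE these were 69 of 368 values and 4 of 23 genes. For the IgG difference between HEC-1-A and KLE they were 206 of 758 and 13 of 38. For IgA in KLE labelled PIGR transduction they were 12 of 1264 and 72 of 79.

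Without the filter, genes were 9 for IgA in KLE (0 with it), 115 for IgA against IgG in KLE (74), 28 for IgG in KLE labelled PIGR transduction (2), and 30 (10) and 728 (399) for the differences of the IgG effect between the KLE sets and between HEC-1-A and KLE, and lists were 9 for IgG (5) and 8 for IgA against IgG (5) in KLE. DESeq2 gave 3, 131, 10, 38 and 1012 genes for the same 5 results and 249 (144) for IgG in KLE. A fit on 2 groups gave 7 for IgA in KLE and 39 for IgG in the labelled set. A stricter filter gave 6 for IgG in the labelled set, an r of -0.081 (0.316) between IgA and IgG in HEC-1-A, a reversal, and an r of 0.281 (0.156) between the IgA effects of the labelled set and HEC-1-A. Thinning to equal totals, which leaves KLE IgA replicate 2 with fewer counts outside mitochondrial ribosomal RNA (24.7% of its counts), gave 2 lists (5) for IgA in KLE, 4 genes for IgG in the labelled set and 17 for the IgG difference between the KLE sets. RLE scaling gave 187 higher and 298 lower (219 and 180) for the IgG difference between lines. The offset gave 1 list for IgA in KLE, 3 each for IgG and for IgA against IgG in KLE, and 113 genes for the last, 39 higher and 74 lower (18 and 56). Without RN7SL1 and mitochondrial genes the IgG difference between the KLE sets had 1 list (2). With the own spread and scaling of each table the IgG difference had 30 genes (10) between the KLE sets and 615 (399) between lines, 287 higher and 328 lower (219 and 180). The IgA difference between lines then had 3287 (3082), 1528 higher and 1759 lower (1689 and 1393).

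With an estimated correlation, lists fell to 0 for the 3 comparisons in KLE (5 each), for IgG in the labelled set (3) and for the differences of the IgG effect (2 and 10), to 10 for IgA against IgG in the labelled set (16), 4 for IgG in HEC-1-A (15), 8 between the untreated KLE sets (14) and 10 for the IgA difference between the KLE sets (17). fry gave 0 for the 3 comparisons in KLE, for IgG in the labelled set and for the IgG difference between the KLE sets.

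Same-numbered libraries did not deviate together (correlations from -0.029 to 0.052, and 5, 4 and 0 of 9 libraries in KLE, the labelled set and HEC-1-A were closest to their own number). These values gave no sign that the numbers pair the samples, but they cannot exclude it. The replicate block gave 117 genes for IgA against IgG in KLE and 19 for the IgG difference between the KLE sets. The block with the offset gave 1, 3 and 3 lists for the comparisons in KLE, 241 genes for IgG and 187 for IgA against IgG in KLE, and 4 for IgG in the labelled set.

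Leaving out 1 library gave 0 to 5 genes and 0 to 6 lists for IgA in KLE, 51 to 449 genes and 3 to 5 lists for IgG in KLE, 28 to 260 genes and 3 to 6 lists for IgA against IgG in KLE, 0 to 5 genes and 1 to 4 lists for IgG in the labelled set, and 658 to 1010 genes for IgG in HEC-1-A. It gave 2 to 53 genes for the IgG difference between the KLE sets and 180 to 556 between lines. The r between IgA and IgG was 0.173 (0.385) in KLE without IgA replicate 1, and 0.545 and 0.567 (0.316) in HEC-1-A without untreated replicates 2 and 3. The r of the IgA effects ran from -0.037 to 0.004 between KLE and HEC-1-A and from 0.111 (without HEC-1-A IgA replicate 3) to 0.153 between the labelled set and HEC-1-A. Of genes changed 1.5-fold in simulated counts 52.6% were recovered for IgA in KLE, 49.2% in the labelled set, 50.8% in HEC-1-A and 39.3% for the IgA difference between the KLE sets.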

Other observations

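The lists and tests of this part were all chosen only after the data were seen. The fatty acid list holds SCD, ACSL1 and THRSP, and the metallothioneins hold MT1X, all named above for their extreme folds. The p-values of these lists are therefore not independent of those results, and they were adjusted over the lists of this part alone. IgA lowered fatty acid synthesis and desaturation genes in both sets of cells in which it called genes. In HEC-1-A 12 of 18 tested members fell and 0 rose (median log2 -0.56, camera adjusted p = 6.49e-26, and 9.53e-05 with an estimated correlation), with FADS1 at -1.95 ± 0.10, the synthase FASN at -1.16 ± 0.07 and the elongase ELOVL6 at -1.46 ± 0.09. In KLE labelled PIGR transduction 13 of 21 fell and 0 rose (median -0.22, camera adjusted p = 1.31e-10, and 0.0134 with an estimated correlation), with SREBF1, the transcription factor of this pathway, at -0.75 ± 0.05. In KLE 0 of 21 were called with IgA by edgeR (camera adjusted p = 0.146).

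Metallothioneins, which bind zinc and copper, went in opposite directions with IgA in 2 sets of cells. In HEC-1-A all 3 tested members rose with IgA (MT2A 2.14 ± 0.07, MT1X 3.24 ± 0.30, MT1F 0.98 ± 0.17, camera adjusted p = 6.64e-16, and 0.00156 with an estimated correlation), and with IgG MT2A fell (-0.60 ± 0.07, list median -0.56, camera adjusted p = 0.000373, and adjusted p = 0.0529 with an estimated correlation). In KLE labelled PIGR transduction 3 of 4 fell (MT1F -0.39 ± 0.06, MT2A -0.27 ± 0.05, MT1X -0.66 ± 0.16, camera adjusted p = 0.00167, and 0.0188 with an estimated correlation). These genes are close paralogs, so single members are uncertain, and the difference between the 2 sets was not tested. Cytosolic aminoacyl-tRNA synthetases, which charge tRNAs with amino acids, rose with IgA in 13 of 20 cases and fell in 2 in KLE labelled PIGR transduction (WARS 1.04 ± 0.05, GARS 0.75 ± 0.04, SARS 0.87 ± 0.06, camera adjusted p = 7.37e-22, and 0.000123 with an estimated correlation). WARS, GARS and SARS also belong to the stress list, so this call is not independent of that list. In KLE 0 of 20 were called with IgA by edgeR (camera adjusted p = 0.189), and against IgG the list lay higher (0.0134, and adjusted p = 0.216 with an estimated correlation). In HEC-1-A 6 rose and 5 fell with IgA (camera adjusted p = 0.827), and against IgG 9 rose and 4 fell (0.0161, and adjusted p = 0.232 with an estimated correlation). IgG in HEC-1-A lowered 8 of 20 synthetases (camera adjusted p = 3.04e-06, and adjusted p = 0.0529 with an estimated correlation).

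The tables differed in how many genes had very few counts. A single count was recorded for 354 to 954 genes per library in HEC-1-A, for 1389 to 2631 in KLE and for 933 to 1851 in KLE labelled PIGR transduction. In the same order, median totals were 37.7, 37.4 and 30.4 M, with ranges of 30.1 to 44.6, 13.4 to 57.8 and 22.0 to 42.9 M. The common dispersion was 0.0827 in HEC-1-A, 0.00809 in KLE and 0.00883 in KLE labelled PIGR transduction.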
